A study of Mus musculus with 6 samples.

How the data were processed

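Liver cells of 6 female mice were profiled by droplet single-cell RNA sequencing with 10x Genomics reagents, 1 library per mouse. The mice were of FVB/NJ, an inbred laboratory strain. Per the labels' protocols, each carried a mammary fat pad graft of Fo5, a tumour line from mice that express human HER2 from a mammary tumour virus promoter. A group of 3 mice received vehicle buffer and a group of 3 received an anti-HER2/CD3 T cell-dependent bispecific antibody (TDB), 1 tail vein injection each. A TDB binds a tumour antigen with 1 arm and the CD3 chain of the T cell receptor with the other. The labels give a dose of 5 mg/kg as the default and 24 h between injection and harvest. Livers were perfused, a lobe was dissociated with an enzyme kit, red cells were lysed in repeated rounds and the suspension was strained. The labels name no sort or enrichment of any cell type, and perfused and strained suspensions can lose large or fragile cells such as hepatocytes.

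The authors deposited a table of whole-number counts per gene and cell and a second table with 1 line per cell. Reads were aligned with GSNAP to the mouse genome build GRCm38, per the submitters' processing notes. The GSNAP version, the counting tool, the gene annotation and whether counts are of unique molecules are not given in the sources used here. The count table held 52636 gene identifiers and 23736 cells, and its column sums equalled the count sum deposited for each cell in 100% of the cells. The deposited table of cells gives, per the labels of its columns, the library, a class name and the percent of counts from mitochondrial genes. No cell had fewer than 500 counts and the highest mitochondrial value the authors list was 24.9 percent, so the deposited cells had been filtered. No value column belonged to a sample outside these 6. Gene symbols and coordinates came from GENCODE M21 on GRCm38, which held 52403 of the identifiers (99.56%); the other 233 had no symbol.

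Cells were taken as deposited, in the 26 classes of the authors' annotation. Before classes were compared, the 10 genes with the highest fold of each class over the other cells were set against marker lists fixed before the data were examined. EC1 to EC6 were summed as endothelial cells, Tcells1 and Tcells2 as T cells (and also kept apart as T cells 1 and T cells 2), and Kupffer1 to Kupffer5 as Kupffer cells. M1 and M2 carried neutrophil markers, M3 and M5 monocyte markers, M4 plasmacytoid dendritic cell (pDC) markers and Tcells3 natural killer (NK) cell markers; they are called neutrophil-like, monocyte-like, pDC-like and NK-like. Own clusters placed 359 cells of M3 with monocytes and 149 with conventional dendritic cells, and 378 cells of Tcells3 with NK cells and 346 with T cells, so both classes are mixed. They placed 188 of 194 cells of Kupffer5 and 105 of 460 of Kupffer4 with endothelial cells; both were summed with the Kupffer cells. Tcells4, EC/T, M6 and M7 stayed unnamed, because their leading genes belonged to several cell types or to platelets. M8 carried neutrophil markers but was kept apart unnamed, with 52 of its 56 cells in own endothelial clusters, and was added to the neutrophil-like cells in an alternative. A class was tested only if every library held at least 20 of its cells; hepatocytes and the unnamed classes were described by values. Scrublet's automatic threshold called 0.18% to 3.44% of the cells of a library, and a fixed score was chosen after this had been seen. Run per library with that score threshold of 0.25, Scrublet called 497 cells doublets (2.09%). They were kept, and removed in an alternative that was planned before, though its score was not. They made up 73.9% of EC/T, 69.6% of M8 and 35.6% of Kupffer5.

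Counts were summed per mouse and class, since cells are not replicates. Sums were compared between TDB and vehicle with edgeR's quasi-likelihood test after filterByExpr and TMM normalization, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are log2 of TDB over vehicle with their standard errors (SE), and levels are CPM (counts scaled by library size) of the class with the SD over 3 mice. The response of endothelial cells was compared with that of 7 other cell types in an edgeR model with the mouse as a block and a term for the difference of the responses. A set of 30 gene lists, fixed before the data were examined, was tested with limma's camera at a preset correlation of 0.01, and again with the correlation estimated from the data and with fry. fry tests whether a list's genes move, on balance, in a single direction, and does not compare the list with other genes. Some genes belong to more than 1 list. Shares of cells were compared with edgeR on cells per class and with an exact two-sided permutation test, whose smallest possible p with 3 against 3 mice is 0.1. Ratios that rest on 1 to 3 counts are given with a 95% counting interval, and ratios to 0 counts as a lower bound against a floor of 3 counts over the group. Both cover counting error only. After the data had been seen, the CPM of each gene in TDB cells of a class was set against its CPM in TDB endothelial cells, and against the median of that percentage over the endothelial markers tested in the class, as a level of endothelial RNA carried along. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11, scanpy 1.11.5, leidenalg 0.10.2, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

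Named genes followed a rule fixed before the data were examined. It took a set of genes chosen in advance for endothelial, T and Kupffer cells, whatever their test gave; 1 of these is not reported here. It added the genes with the largest rises and falls among those past the threshold, with a mean log2 CPM of at least 5 and no overlap between groups: 6 and 6 in endothelial cells, 4 and 4 elsewhere. It also added up to 2 members of each list that rose and 2 that fell. Predicted genes, receptor variable segments and X-inactivation genes were left out, and not every list member was named. With 3 against 3 mice, groups fail to overlap by chance for 10% of genes. Gene families with near-identical copies, namely the guanylate-binding proteins (Gbp), Ifit3 and Ifit3b, Tgtp1 and its copy, the haemoglobin chains, H2-Q genes, Saa1 and Saa2 and the Serpina3 genes, are uncertain, since the authors' treatment of shared reads is not given.

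The labels give both groups the replicate numbers 1, 4 and 5. Deviations from the group means correlated between same-numbered libraries in the endothelial sums (r across genes, which are not independent, of 0.569, 0.294 and 0.471) and in the sums over all cells (0.567, 0.283 and 0.386). In the other classes at least 1 pair lay at or under 0.1. In the endothelial sums, differently numbered pairs lay at 0.107 (vehicle 4 and TDB 5) and 0.158 (vehicle 5 and TDB 4). Those with a replicate 1 lay at -0.465 to -0.308. Part of this is built in, since deviations within a group cancel. Library identifiers in the cell names also set replicate 1 of both groups apart from 4 and 5. A grouping of 1 against 4 and 5 was not modelled. The labels do not say what the numbers mark. The fit with the number as a block was an alternative. It is mentioned, in some cases without its value, where it ended or made a call or moved a count by over 1.5 times. Pairs of libraries within a group were compared in the endothelial sums and the sums over all cells, and none agreed within sampling noise. In the endothelial sums chi-square per degree of freedom was 6.45 to 21.2.

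Alternatives fixed before the data were examined were DESeq2 size factors, DESeq2's Wald test, no filter on low counts, the replicate block, leaving out each library, removal of called doublets, a stricter cell filter (at least 500 counts and 300 genes and under 10% mitochondrial counts, which kept 22815 cells), equal numbers of cells per library, a test against a fold change of 1.5, other denominators for shares and own clustering of the cells. Other class definitions were added after seeing the data: endothelial cells with EC/T, without EC6 or from EC1 to EC3 alone, all 4 T cell classes, Kupffer cells without Kupffer5 or from the deep classes alone, and neutrophil-like cells with M8. So was the camera test on differences between cell types. The edgeR steps were tested on simulated counts drawn from the means and library sizes of the real libraries with 200 genes changed. In the simulated endothelial comparison of 12755 genes, 17.9% of genes changed 1.5-fold, 76.1% of those changed 2-fold and 97% of those changed 4-fold were recovered, with 14 false calls. In a simulated list test, the changed list was called, along with 2 lists that share members with it and 0 others. Each gene was drawn independently there, so the simulation could not show list calls that come from genes varying together.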

Results

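The data were counts per gene in 23736 liver cells, 12170 from 3 vehicle mice and 11566 from 3 TDB mice, harvested 24 h after injection. Vehicle libraries 1, 4 and 5 held 2933, 3925 and 5312 cells with 20702001, 16038478 and 25563794 counts. TDB libraries 1, 4 and 5 held 2678, 3765 and 5123 cells with 23065363, 22361138 and 34609604 counts. The median cell had 4747, 3281 and 3622 counts in the vehicle libraries and 4806, 3915 and 4472 in the TDB libraries. Depth differed more within some classes: medians per library were 3782.5 to 4211 in vehicle and 7144 to 8107.5 in TDB mice for T cells 2, 2823 to 3452 and 5492 to 6105 for NK-like cells, and 997 to 12991.5 and 6060.5 to 37085 for Kupffer cells. Over both groups endothelial cells were the most numerous class (6141 vehicle and 5428 TDB cells), followed by Kupffer cells (1896 and 1605), the resident macrophages of the liver, and T cells (1346 and 1883). In TDB mice T cells outnumbered Kupffer cells. B cells (790 and 570), neutrophil-like (551 and 625), NK-like (477 and 247), monocyte-like (223 and 475) and pDC-like cells (212 and 270) were smaller classes. The edgeR p-values weigh a difference against the spread between mice. Those of camera compare the genes of a list with other genes, at a preset or estimated correlation.

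The first comparison asked how liver endothelial cells had changed a day after the antibody, the question named by the title of the series. Transcripts of Cxcl9 and Cxcl10, chemokines that attract activated T cells, were among the 6 largest rises under the naming rule. Cxcl9 went from 33.5 ± 1.08 to 5174 ± 1973 CPM (mean ± SD, n = 3 mice per group), a log2 fold change of 7.27 ± 0.31 (SE, adjusted p = 4.54e-06 by edgeR's quasi-likelihood test). Cxcl10 went from 26.2 ± 3.54 to 2454 ± 1036 CPM (6.54 ± 0.38, adjusted p = 1.68e-05). Cd274, which encodes the checkpoint ligand PD-L1, rose from 13.4 ± 0.887 to 550 ± 170 CPM (5.35 ± 0.26, adjusted p = 6.54e-06). Vcam1 and Icam1, adhesion molecules that bind leukocyte integrins, rose by 2.54 ± 0.17 (from 30.6 ± 2.60 to 178 ± 41.4 CPM, adjusted p = 3.33e-05) and 1.37 ± 0.10 (from 60.5 ± 1.69 to 156 ± 16 CPM, adjusted p = 4.71e-05). The selectins Sele and Selp, which slow rolling leukocytes, lay at 2.82 ± 2.27 and 11.9 ± 4.06 CPM in vehicle and 1.99 ± 0.443 and 9.56 ± 1.40 CPM in TDB mice, and neither passed the test (adjusted p = 0.605 and 0.468).

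In total 2148 of 12901 genes tested in endothelial cells passed the threshold, 1164 higher and 984 lower after TDB. The count was 940 without the library vehicle 4, 957 without TDB 5 and 1439 to 2089 on leaving out each of the other 4, and 3528 with the replicate number as a block. The largest rises under the naming rule were those of Cxcl9, Gbp11 (7.01 ± 0.42), Zbp1, a sensor of Z-form nucleic acids (7.01 ± 0.59), Igtp, an interferon-induced GTPase (6.54 ± 0.28), Cxcl10 and Gbp2b (6.22 ± 0.38). Ubd, a ubiquitin-like protein, had 0 counts in vehicle and 153 in TDB cells and was at least 66.1-fold higher (adjusted p = 0.000856). Vehicle counts came mostly from the authors' classes EC2 (72.7%), EC3 (15.4%), EC5 (6.02%) and EC6 (5.69%). TDB counts came from EC1 (86.9%) and EC4 (10.1%), so the values compare different clusters of the same cell type.

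Among the largest falls, Btnl9, a butyrophilin-like gene of endothelium, dropped from 338 ± 24.1 to 101 ± 35.4 CPM (-1.74 ± 0.21, adjusted p = 0.000974), and Slc18a2, a vesicular monoamine transporter, from 58.1 ± 7.49 to 18.5 ± 8.12 CPM (-1.64 ± 0.26, adjusted p = 0.00393). The others were markers of other cells: the bile duct genes Spp1 (-6.45 ± 0.43) and Clu (-1.86 ± 0.29), and the haemoglobin genes Hbb-bs (-4.54 ± 0.93) and Hba-a1 (-3.56 ± 0.77). The 10 vehicle cells with most counts held 98.5% of the vehicle counts of Spp1, 73.5% of Clu, 87.7% of Hbb-bs and 81.9% of Hba-a1, against 1.9% of Btnl9 and 4.2% of Slc18a2. Without EC6, Spp1 was at -4.18 ± 1.41 (adjusted p = 0.0775) and Clu at -0.93 ± 0.48 (adjusted p = 0.237). Calls of Hbb-bs and Hba-a1 were lost without TDB 4 (-4.10 and -3.24) and without TDB 5 (-4.45 and -3.22). Epcam, an epithelial marker, fell by 3.39 on the log2 scale, with 81.9% of its vehicle counts in 10 cells.

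Gene lists placed these genes in groups. All 38 tested members of the interferon gamma list rose in endothelial cells, among them Igtp, Gbp2b and Cd274 (camera adjusted p = 3.27e-49, adjusted p = 0.121 with an estimated correlation), and 38 passed when adjusted over the list alone. Of the type I interferon list, 27 of 30 members rose, such as Rsad2, an antiviral enzyme (3.66 ± 0.15) (adjusted p = 1.59e-30, adjusted p = 0.121 with an estimated correlation; 29 adjusted over the list alone). Of MHC class I presentation genes 20 of 21 rose, including Nlrc5, a transactivator of class I genes (4.19 ± 0.20), and the peptide transporter Tap1 (3.77 ± 0.19) (adjusted p = 3.88e-25, adjusted p = 0.121 with an estimated correlation; 20 adjusted over the list alone). Of MHC class II genes 8 of 9 rose, with the class II transactivator Ciita going from 0.177 to 15.6 CPM (6.52 ± 0.69) and H2-DMa from 1.82 to 76.5 CPM (5.36 ± 0.68). Their list had adjusted p = 9.5e-05, or adjusted p = 0.455 with an estimated correlation, and 8 adjusted over the list alone. The list of checkpoint and regulatory ligands had 4 of 8 members higher, among them Il18bp, a decoy for interleukin 18 (4.19 ± 0.12) (adjusted p = 0.001, adjusted p = 0.211 with an estimated correlation; 5 adjusted over the list alone).

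Of 13 chemokines 6 rose, including the monocyte attractant Ccl2 (1.04 ± 0.524 to 17.5 ± 9.42 CPM, 4.03 ± 0.46; list adjusted p = 8.62e-05, adjusted p = 0.121 with an estimated correlation; 6 adjusted over the list alone). NF-kB and TNF response genes had 9 of 25 higher, Vcam1, Icam1 and Ccl2 among them (adjusted p = 9.18e-05, adjusted p = 0.211 with an estimated correlation; 9 adjusted over the list alone). Of the adhesion molecules 5 of 15 rose and 0 fell, with camera adjusted p = 0.0792 (adjusted p = 0.279 with an estimated correlation), fry adjusted p = 0.00076, and 6 higher and 2 lower adjusted over the list alone. Acute phase proteins had 8 of 23 higher (adjusted p = 0.000107, adjusted p = 0.273 with an estimated correlation; 9 adjusted over the list alone). Apoptosis and p53 genes had 5 of 20 higher and 1 lower, with the cell cycle inhibitor Cdkn1a at 1.54 ± 0.20 and Mlkl, the effector of necroptosis, at 1.51 ± 0.11 (adjusted p = 0.00295, adjusted p = 0.133 with an estimated correlation; 6 and 1 adjusted over the list alone). Of 10 T cell homing receptors 2 rose, the integrins Itga1 (1.53 ± 0.12) and Itgb7 (1.85 ± 0.17) (adjusted p = 0.048, adjusted p = 0.439 with an estimated correlation; 2 adjusted over the list alone). In other splits of the 6 mice camera called up to 113 lists over all classes against 111 for the real groups, a limit on all list tests here. That other split, vehicle 1, vehicle 4 and TDB 5 against the rest, parts all 3 same-numbered pairs, as do splits with 91 and 64 lists.

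Markers of the sinusoidal endothelium, the fenestrated lining of the liver, moved both ways: 4 of 22 rose and 6 fell (adjusted p = 0.0889, adjusted p = 0.557 with an estimated correlation; 4 and 7 adjusted over the list alone), and the list was lower with the replicate block (adjusted p = 0.0412). Il6st, the shared receptor chain for interleukin 6 (1.37 ± 0.24), F8, which encodes clotting factor VIII (0.68 ± 0.10), and Cd209b (0.68 ± 0.12) rose. The scavenger receptor Stab2 went from 1478 ± 81.5 to 1014 ± 77.8 CPM (-0.54 ± 0.10, adjusted p = 0.00858, or -0.51 ± 0.12 and 0.0509 without vehicle 4), and the lectin Clec4g from 5354 ± 156 to 3996 ± 191 CPM (-0.42 ± 0.10, adjusted p = 0.0225). The call of Clec4g was lost without vehicle 4 (-0.42), vehicle 5 (-0.40), TDB 4 (-0.40) or TDB 5 (-0.47). Lyve1 (-0.17 ± 0.12, adjusted p = 0.381), Kdr, the main receptor for vascular endothelial growth factor (-0.24 ± 0.11, adjusted p = 0.174), and Cd34 (-0.02 ± 0.15, adjusted p = 0.935) did not pass; Kdr passed with the replicate block. Of 12 coagulation genes F8 and 1 other rose and 2 fell (adjusted p = 0.834). Tfpi, the inhibitor of the tissue factor pathway, fell from 494 ± 9.60 to 274 ± 9.19 CPM (-0.85 ± 0.08, adjusted p = 0.000291).

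The other lists did not pass in endothelial cells. They covered junctions and growth factor receptors (2 of 20 higher and 2 lower, adjusted p = 0.919), the pericentral zone (1 of 10 lower, 0.141) and the periportal zone (2 of 10 lower, 0.0792). Stress genes of dissociation went both ways, with 8 of 22 higher and 4 lower (0.402); Atf3 rose by 2.34 ± 0.27 while Fos fell by 1.63 on the log2 scale. Cell proliferation had 1 of 22 members lower (0.863), the centromere gene Cenpa. Mitochondrially encoded genes had 0 of 13 past the threshold (adjusted p = 0.834; 0 adjusted over the list alone). Stellate cell and matrix genes had 1 of 12 higher and 1 lower (0.736). Lists of other cells were those of T cell activation (5 of 16 higher and 1 lower, 0.0718), naive T cells (0 of 10, 0.599), the T cell receptor (0 of 7, 0.834), Kupffer identity (3 of 15 higher and 4 lower, 0.227), macrophage activation (3 of 10 higher and 1 lower, 0.33), neutrophil activation (2 of 13 higher, 0.353), hepatocyte markers (1 of 17 lower, 0.0685), hepatocyte metabolism (1 of 18 lower, 0.599), epithelium (2 of 5 lower, 0.298) and red cells and platelets (1 of 8 higher and 3 lower, 0.0685, or 0.0104 with the replicate block).

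**Figure D1:**
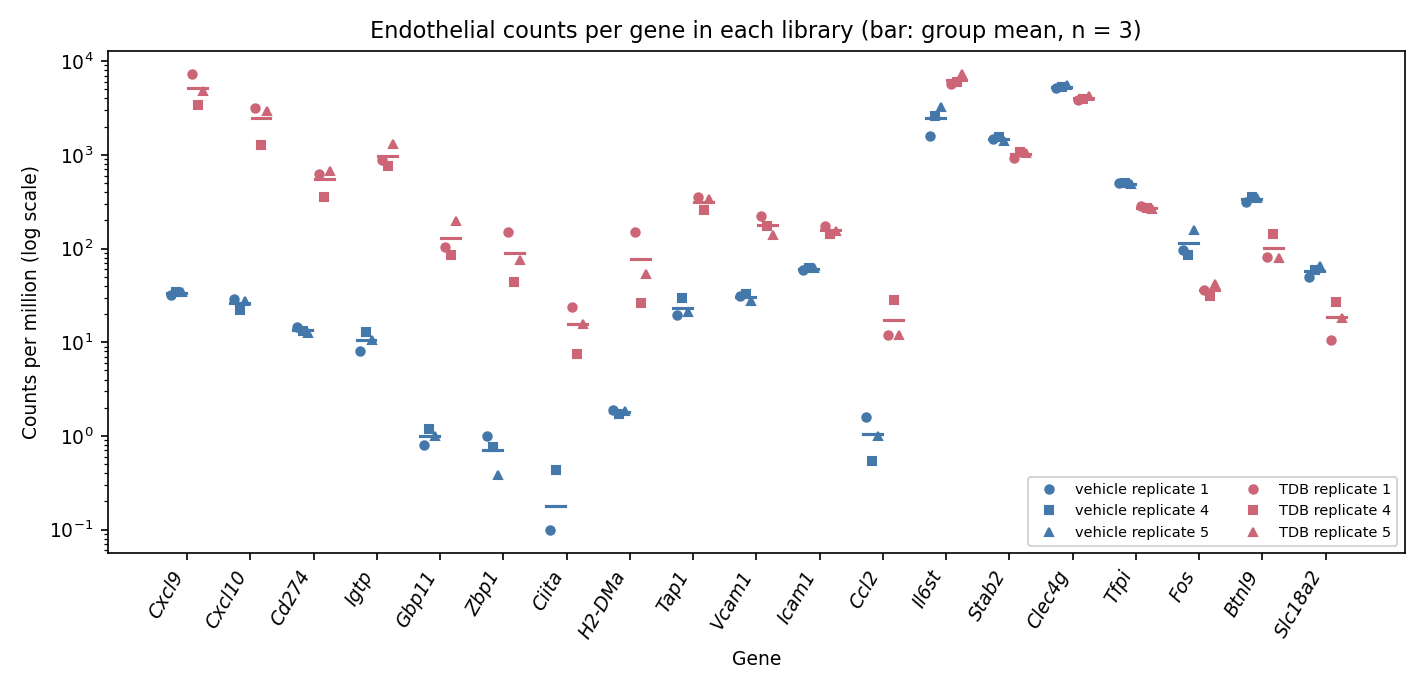
CPM in endothelial cells on a log scale, 1 point per library, for named genes in 3 vehicle and 3 TDB mice; the Ciita value of vehicle 5 is 0 and is not drawn. Cxcl9 lies at a mean of 33.5 CPM in vehicle and 5174 CPM in TDB mice, and Stab2 at 1478 and 1014 CPM.

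The second comparison asked whether the endothelial response differed from that of other liver cells, by testing the difference of the log2 fold changes. The rise of Cd274 was greater in endothelium than in NK-like cells (difference 4.79 ± 0.44), B cells (3.77 ± 0.27), T cells (3.72 ± 0.31), monocyte-like (3.45 ± 0.36), pDC-like (2.94 ± 0.56) and Kupffer cells (2.47 ± 0.25), with adjusted p of 0.0109 or less. In neutrophil-like cells the difference was 0.84 ± 0.33 (adjusted p = 0.228), 0.04 without vehicle 5, and past the threshold without vehicle 1 (1.47) or TDB 4 (1.17). The pDC-like difference did not pass without vehicle 4 (2.32). H2-DMa, which loads peptides on MHC class II, and Igtp had the same pattern: differences to 6 types passed, from 3.84 (Kupffer) to 5.34 (NK-like) for H2-DMa and from 2.21 (B cells; not past without vehicle 1, at 1.74) to 6.20 (NK-like) for Igtp. Those to neutrophil-like cells did not (0.81 ± 1.79 and 0.16 ± 0.50) and changed sign when single libraries were left out. Atf3, a stress-induced transcription factor, rose in endothelium, and its log2 fold change was greater there than in all 7 types. Differences were 1.40 (Kupffer) to 3.40 (T cells). That to NK-like cells was 2.00 ± 0.58, and 3.58 without TDB 4. The log2 fold change of Atf3 was 0.861 in Kupffer and 0.025 in B cells. It was -1.149 to -0.71 in T, monocyte-like, pDC-like and neutrophil-like cells. Calls of Atf3 were lost for NK-like cells without vehicle 1 (1.12) or TDB 5 (1.27), for pDC-like cells without vehicle 5 (2.54) or TDB 5 (2.53) and for B cells without vehicle 5 (2.32). Rsad2 went the other way between cell types: its rise was greater in endothelium than in Kupffer cells (3.56 ± 0.21) and smaller than in neutrophil-like cells (-2.61 ± 0.46, adjusted p = 2.98e-06).

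By list, interferon gamma genes responded more in endothelium than in T cells (29 of 37 members greater, 0 smaller), NK-like (28 and 0), Kupffer (29 and 1), pDC-like (14 and 0), monocyte-like (13 and 0) and B cells (9 and 0). The camera adjusted p was 2.91e-13 or less for these, and adjusted p = 0.0625 to 0.213 with an estimated correlation. Against neutrophil-like cells 1 was greater and 7 smaller (adjusted p = 0.312), and 18 of 32 type I interferon genes responded less in endothelium (adjusted p = 2.65e-27, adjusted p = 0.113 with an estimated correlation). MHC class I genes responded more in endothelium than in monocyte-like (11 of 21) and pDC-like cells (11 of 21), calls that held with an estimated correlation (adjusted p = 0.0213 and 0.0395). So did stress genes against pDC-like cells (8 of 22 greater, adjusted p = 0.0395). Proliferation genes responded less in endothelium than in Kupffer cells (25 of 26 smaller, adjusted p = 3.32e-13, adjusted p = 0.172 with an estimated correlation).

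Counts of genes whose response differed were 4923 for Kupffer, 1113 for NK-like, 600 for T, 249 for neutrophil-like, 249 for B, 221 for monocyte-like and 194 for pDC-like cells. In the T cell comparison the response was greater in endothelium for 312 genes and smaller for 288, against 353 and 170 with DESeq2 size factors. That count was 272 without vehicle 1, 230 without vehicle 4 and 357 without vehicle 5. The monocyte-like count was 563 without TDB 1, 110 without vehicle 4 or vehicle 5, and 115 without TDB 4 or TDB 5. The neutrophil-like count was 127 without vehicle 1, 160 without vehicle 4 and 150 without TDB 5, the pDC-like count 77 without TDB 5, and the B cell count 148 without vehicle 5 and 377 without TDB 1. In the simulated comparison with T cells 3% of 1.5-fold, 26.9% of 2-fold and 80.3% of 4-fold differences were recovered. Genes higher in both endothelium and another type numbered 572 for Kupffer cells (276.7 if independent), 196 for monocyte-like (39.6), 184 for neutrophil-like (43.7), 115 for NK-like (78.5), 101 for T (38.4), 98 for B (13.9) and 75 for pDC-like cells (11.5). The mice are the same in each pair.

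**Figure D2:**
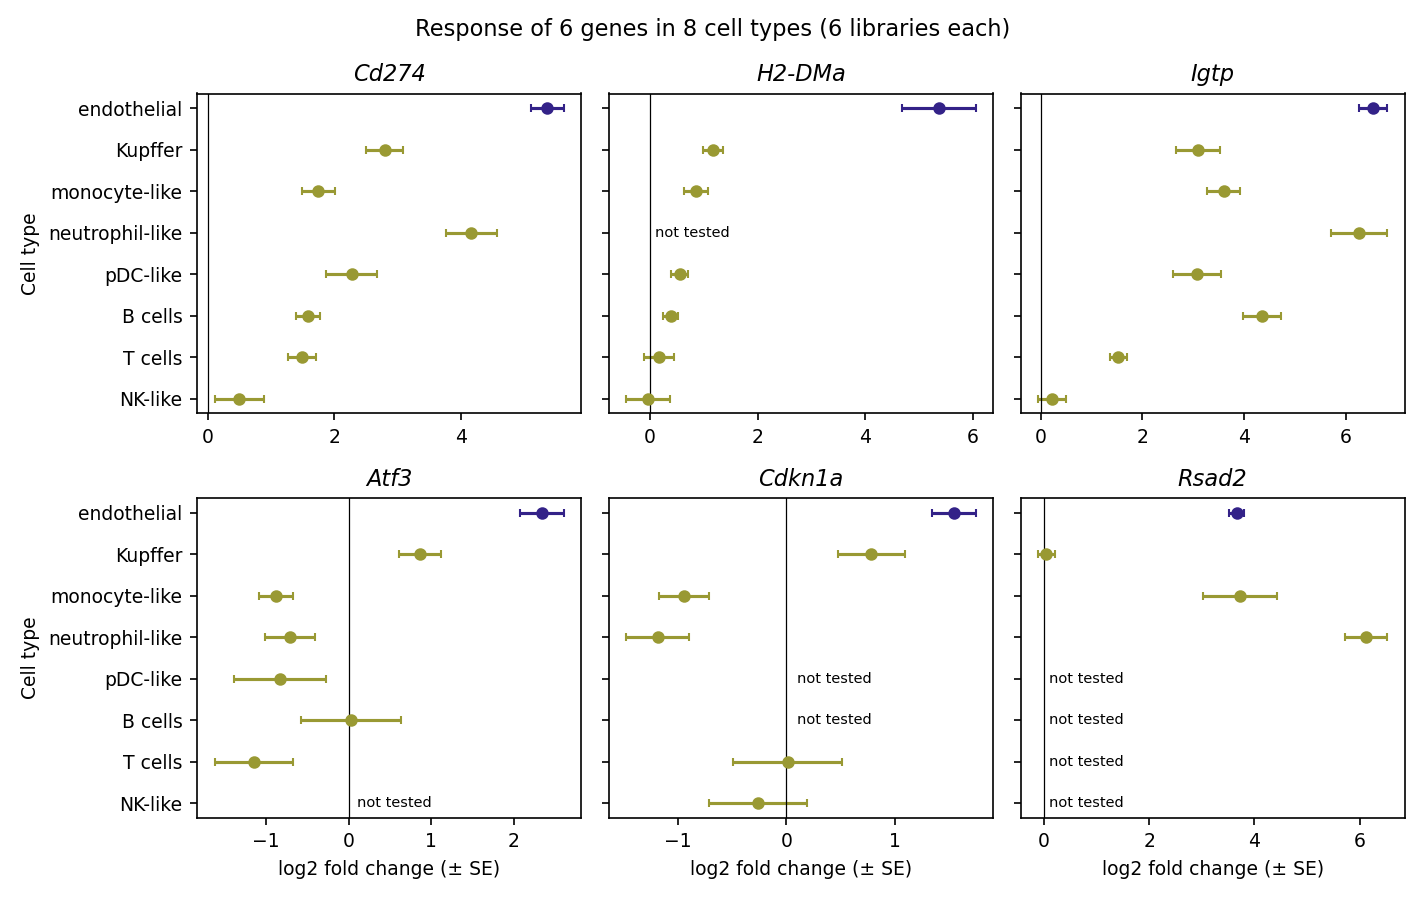
Log2 fold change of TDB over vehicle with its SE for 6 genes in 8 cell types, 3 mice per group; types in which a gene was not tested are marked. Cd274 lies at 5.35 in endothelial cells and 0.50 in NK-like cells.

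T cells carry the CD3 chain that the antibody binds. T cells 1 had the naive T cell genes Lef1, Satb1 and Il7r among its 10 leading genes, after T cell receptor and CD3 genes. In this class 166 of 7214 genes changed, 105 higher and 61 lower. The interferon-induced GTPase Iigp1 rose from 8.53 ± 2.49 to 117 ± 66.7 CPM (3.75 ± 0.46, adjusted p = 0.000195), Gbp2 by 2.85 ± 0.20, Ly6a by 2.71 ± 0.30 and Cd274 by 2.46 ± 0.33. The transcription factor Irf8 (3.55 ± 0.46), the activation-induced factor Irf4 (3.43 ± 0.58) and the co-receptor Cd8a (1.45 ± 0.19) also rose. Tsc22d3, a glucocorticoid-induced gene, fell by 1.43 and the chemokine receptor Cxcr4 by 1.29 on the log2 scale. Cd3e (0.13 ± 0.11), the activation marker Cd69 (-0.42 ± 0.26) and Ccr7 (-0.28 ± 0.16) did not pass; Cd69 passed without TDB 4 (-1.005). Of interferon gamma genes 29 of 32 rose (adjusted p = 2.42e-48, adjusted p = 0.106 with an estimated correlation; 30 adjusted over the list alone), and of MHC class I genes 10 of 19 (adjusted p = 6.91e-18, adjusted p = 0.106 with an estimated correlation; 16 adjusted over the list alone). Proliferation genes had 0 of 9 past the threshold (adjusted p = 0.416; 0 adjusted over the list alone). Clec4g, an endothelial gene, fell by 1.23 on the log2 scale in these cells, a call lost without vehicle 1 (-0.96), vehicle 5 (-1.25) or TDB 4 (-1.03).

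In T cells 2, with Ccl5, Nkg7 and Cxcr6 among its 10 leading genes, 1674 of 7417 genes changed, 976 higher and 698 lower. Among the largest rises, E2f1, a factor that drives S phase entry, went from 3.13 ± 1.39 to 58.8 ± 19.5 CPM (4.10 ± 0.46, adjusted p = 2.73e-05), and Cdc6 rose by 3.40 ± 0.46 and Tk1 by 3.19 ± 0.36. Mcm3, a member of the proliferation list, rose by 2.81 ± 0.25. The proliferation list had 14 of 25 members higher and 2 lower (adjusted p = 2.03e-07, adjusted p = 0.266 with an estimated correlation; 16 and 3 adjusted over the list alone). The lower members were Cenpa (-1.87 ± 0.37) and Ccnb2, both genes of the G2 and M phases, the latter lost without vehicle 1 (-0.88), vehicle 4 (-1.45), TDB 1 (-0.95) or TDB 4 (-1.21), and at -2.10 without TDB 5. Mki67 was at 0.88 ± 0.33 (adjusted p = 0.0656), and passed with the replicate block and without vehicle 1 (1.48) or TDB 1 (1.00), and was at -0.065 with equal cells per library. Gzmb, a cytotoxic protease, rose from 42.4 ± 18.6 to 174 ± 72.5 CPM (2.10 ± 0.32, adjusted p = 0.000367). In the T cell activation list 11 of 28 genes fell, Gzmb alone rose and 16 did not pass (adjusted p = 0.000202, adjusted p = 0.216 with an estimated correlation; 2 higher and 14 lower adjusted over the list alone). Ccl5 went from 2337 ± 315 to 891 ± 320 CPM (-1.39 ± 0.20), the inhibitory receptor Ctla4 from 201 ± 59.5 to 69.9 ± 3.62 CPM (-1.53 ± 0.19) and Cd69 from 174 ± 3.08 to 91.9 ± 14.3 CPM (-0.94 ± 0.15). Ifng went from 294 ± 117 to 177 ± 28.3 CPM (-0.76 ± 0.21, adjusted p = 0.0183), a call lost without vehicle 5 (-0.33), TDB 1 (-0.64) or TDB 4 (-0.73). Cells of T cells 2 held more counts after TDB (library medians of 7144 to 8107.5, against 3782.5 to 4211 in vehicle). CPM are shares of these counts, so a fall in CPM in this class does not by itself show a fall per cell.

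Further lists fell in T cells 2: naive and recirculation genes (8 of 13 lower, among them the interleukin 7 receptor Il7r at -1.87 ± 0.19, adjusted p = 1.86e-05, adjusted p = 0.211 with an estimated correlation; 9 adjusted over the list alone), NF-kB genes such as Tnfaip3 and Rel (7 of 16 lower, adjusted p = 0.000124, adjusted p = 0.211 with an estimated correlation; 7 adjusted over the list alone), homing receptors such as Cxcr4 and Itga4 (4 of 15 lower, adjusted p = 0.00806, adjusted p = 0.211 with an estimated correlation; 4 adjusted over the list alone) and stress genes (14 of 21 lower and 1 higher, adjusted p = 8.06e-06, adjusted p = 0.301 with an estimated correlation; 16 and 2 adjusted over the list alone). The interferon gamma list had 13 of 30 members higher (adjusted p = 0.000552, adjusted p = 0.257 with an estimated correlation; 15 higher and 1 lower adjusted over the list alone). All 7 tested hepatocyte markers were lower in the same sums, such as Fabp1 (70.1 ± 10.9 to 16.6 ± 3.92 CPM, adjusted p = 2.23e-05, adjusted p = 0.211 with an estimated correlation). Cd3e (-0.31 ± 0.11, adjusted p = 0.0604), Il2ra (-0.46 ± 0.18) and Ccr7 (-0.95 ± 0.40) did not pass; Cd3e passed without vehicle 1 (-0.34) and with DESeq2 size factors, Il2ra without TDB 5 (-0.66) and Ccr7 with the replicate block. The count of changed genes was 1043 without vehicle 5 and 1084 without TDB 5.

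Summed over both classes, 551 of 9165 T cell genes changed (407 higher and 144 lower), but the count was 69, 37 and 54 without vehicle 1, 4 or 5, and 180, 928 and 352 without TDB 1, 4 or 5. With the replicate block it was 900. T cells 1 supplied 65.0% of the counts in vehicle and 53.7% in TDB mice, and 890 of its cells came from TDB 4, against 187 to 333 in each other library. In the sums Gzmb was at 2.61 ± 0.64 (adjusted p = 0.0427, lost on leaving out any library other than TDB 4, at 1.69 without TDB 5 to 3.11 without vehicle 5), Mki67 at 1.44 ± 0.52 (adjusted p = 0.139, past with the replicate block and without TDB 4, at 1.86), Ifng at -0.40 ± 0.52 and Il2ra at 0.00 ± 0.37. Tsc22d3 fell by 1.86 and Txnip by 1.45 on the log2 scale. Among interferon gamma genes 27 of 32 were higher (adjusted p = 1.38e-23, adjusted p = 0.24 with an estimated correlation; 29 adjusted over the list alone). For T cells 1 alone the count was 80, 66 and 61 without vehicle 1, 4 or 5, 94 without TDB 4, and 255 with the replicate block. In simulated T cells 1, 10.4%, 62.7% and 90.9% of genes changed 1.5-, 2- and 4-fold were recovered, and in T cells 2 14.9%, 56.7% and 86.4%.

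NK-like cells had 1241 of 5891 genes changed, 685 higher and 556 lower. Rises included those of E2f1 at 3.98 ± 0.57, Cdca7 at 3.99 ± 0.50, Mcm2 at 2.51 ± 0.26 (19.4 ± 6.01 to 115 ± 21.0 CPM) and the mitotic kinase Aurkb at 2.48 ± 0.34. Of proliferation genes 18 of 24 were higher and 0 lower (adjusted p = 1.23e-13, adjusted p = 0.347 with an estimated correlation; 19 adjusted over the list alone). Gzmb rose from 1554 ± 241 to 3355 ± 929 CPM (1.12 ± 0.15) and the activation receptor Tnfrsf9 by 1.66 ± 0.33, while Ccl5 fell from 21660 ± 4397 to 8845 ± 1128 CPM (-1.29 ± 0.11) and the interleukin 18 receptor Il18r1 from 196 ± 12.5 to 37.1 ± 15.3 CPM (-2.32 ± 0.22). Of recirculation genes 6 of 8 fell, such as Klf2, which maintains lymphocyte trafficking receptors (-1.69 ± 0.17), and Il7r (-3.36 ± 0.43) (adjusted p = 0.000131, adjusted p = 0.249 with an estimated correlation; 6 adjusted over the list alone). Stress genes had 11 of 18 lower and 2 higher (adjusted p = 0.000128, adjusted p = 0.657 with an estimated correlation; 12 and 2 adjusted over the list alone): Jun and Fos fell by 1.92 and 1.90 on the log2 scale, and the heat shock members of the list went both ways. Interferon gamma genes had 8 of 23 higher and 2 lower, and their list did not pass (adjusted p = 0.0631). Hepatocyte markers had 4 of 5 lower (adjusted p = 0.0318, adjusted p = 0.544 with an estimated correlation), Fabp1 at -1.42 ± 0.28. The count was 807 without vehicle 5 and 795 without TDB 5, and the class mixes NK and T cells. NK-like cells also held more counts after TDB (library medians of 5492 to 6105, against 2823 to 3452 in vehicle). Their falls in CPM likewise do not by themselves show falls per cell. In simulated NK-like sums, 59.7% of genes changed 2-fold were recovered.

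Kupffer cells had the largest count, 5950 of 12224 genes, 3053 higher and 2897 lower, and 4916 to 5388 with a library left out. Cxcl9 rose from 63.7 ± 50.6 to 1144 ± 61.4 CPM (4.21 ± 0.53, adjusted p = 0.000361), Serpina3g by 4.29 ± 0.63 and Ly6a by 4.201 ± 0.62. Clec4f, the lectin that marks Kupffer cells, fell from 5611 ± 980 to 2546 ± 120 CPM (-1.14 ± 0.15, adjusted p = 0.0004). The scavenger receptor Cd163 fell from 442 ± 149 to 47.1 ± 21.5 CPM (-3.24 ± 0.34), the mannose receptor Mrc1 from 1036 ± 32.8 to 253 ± 26.1 CPM (-2.03 ± 0.12) and the complement receptor Vsig4 from 2657 ± 358 to 888 ± 56.7 CPM (-1.58 ± 0.13), while the scavenger receptor Marco rose by 1.16 ± 0.19 and Acod1, the itaconate-producing enzyme of activated macrophages, by 4.40 ± 0.26. The cytokine genes Il1b (-0.97 ± 0.26) and Il6 (-2.92 ± 0.45) fell. Nos2 did not reach the filter on low counts. Library medians of counts per Kupffer cell were 997 to 12991.5 in vehicle and 6060.5 to 37085 in TDB mice. Falls in CPM in this class, those of Clec4f and Il1b among them, therefore do not by themselves show falls per cell. Proliferation genes had 24 of 26 higher, such as Top2a, from 10.4 ± 5.99 to 132 ± 84.2 CPM (3.71 ± 0.56) (adjusted p = 1.46e-06, adjusted p = 0.771 with an estimated correlation; 24 and 1 lower adjusted over the list alone).

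Interferon gamma genes had 35 of 37 members higher in Kupffer cells (adjusted p = 5.34e-16; 35 adjusted over the list alone), MHC class I genes 18 of 21 (adjusted p = 9.5e-08; 18 alone), with Psmb8, an immunoproteasome subunit, at 2.02 ± 0.16, and MHC class II genes 10 of 12 (adjusted p = 0.000489; 10 alone). All 3 had adjusted p = 0.771 with an estimated correlation. The Kupffer identity list had 7 of 17 lower and 2 higher (adjusted p = 0.0801, adjusted p = 0.771 with an estimated correlation; 7 and 2 adjusted over the list alone). Sinusoidal endothelial genes were lower in Kupffer sums, 18 of 22 with 1 higher (adjusted p = 2.37e-07, adjusted p = 0.771 with an estimated correlation; 18 and 1 adjusted over the list alone). Without Kupffer5, a class of 194 vehicle and 0 TDB cells that supplied 23.4% of the vehicle counts, 5 of these 18 genes were lower and 11 higher. Own clusters placed 188 of the 194 cells of Kupffer5 and 105 of 460 of Kupffer4 with endothelial cells. Vehicle counts otherwise came from Kupffer2 (67.5%), and TDB counts from Kupffer3 (90.5%). In simulated Kupffer sums 20.9%, 53.7% and 92.4% of genes changed 1.5-, 2- and 4-fold were recovered.

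In monocyte-like cells 775 of 8171 genes changed (358 higher and 417 lower), or 1254 (778 higher and 476 lower) with no filter on low counts. The balance also turned to more higher than lower without vehicle 1, vehicle 4, TDB 1, TDB 4 or TDB 5. Cxcl10 rose from 2.04 ± 2.15 to 295 ± 93.5 CPM (6.83 ± 0.45), Iigp1 by 6.52 ± 0.52 and Ly6a by 6.25 ± 0.38, and the antibacterial gene Pglyrp1 fell from 404 ± 78.3 to 58.6 ± 2.59 CPM (-2.77 ± 0.17). In TDB mice Cxcl10 stood at 12% of its endothelial level and endothelial markers at a median of 5.05%, so carried endothelial RNA was not excluded for part of its level. Interferon gamma genes had 31 of 36 higher and 1 lower (adjusted p = 5.21e-35, adjusted p = 0.251 with an estimated correlation; 32 and 1 adjusted over the list alone). The cells came from M3 in TDB mice (99.9% of counts) and from M3 (48.8%) and M5 (51.2%) in vehicle mice. Leading genes of M5 included Ace and Ear2, and those of M3 Ly6c2 and H2-Aa. Changes in monocyte-like cells, the fall of Pglyrp1 among them, were not separated from this shift from M5 to M3. Nor were their differences from endothelium. Monocyte-like cells held more counts after TDB (library medians of 12188 to 15311.5, against 5522 to 10078 in vehicle). Their falls in CPM do not by themselves show falls per cell. The count of changed genes was 405 without vehicle 4, 410 without TDB 4 and 364 without TDB 5. In neutrophil-like cells 423 of 3120 genes changed (306 higher and 117 lower) and all 28 type I interferon genes rose (adjusted p = 2.35e-26, adjusted p = 0.142 with an estimated correlation; 28 adjusted over the list alone). Ifit1, an antiviral gene, had 1 count in vehicle and 276 in TDB cells, a ratio of 231 (counting interval 41 to 9140). Cd274 rose from 68.3 ± 49.5 to 1176 ± 167 CPM (4.16 ± 0.40), the protease Ctss by 4.34 ± 0.32 and Il18bp by 5.00 ± 0.30. A further 29 of 32 interferon gamma genes were higher (adjusted p = 1.62e-28, adjusted p = 0.142 with an estimated correlation; 29 adjusted over the list alone). The cells were M2 in vehicle (99.6% of counts) and M1 in TDB mice (98.0%). The count was 276 without vehicle 1 and 256 without TDB 5. Lower genes numbered 20 (without TDB 5) to 108 (without TDB 4) on leaving out each library, and 45 by DESeq2's Wald test.

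In pDC-like cells 182 of 6524 genes changed (103 higher and 79 lower), and 307 (139 higher and 168 lower) without called doublets. Nlrc5 rose by 2.68 ± 0.37, and Cd69 and Cxcr4 fell by 2.37 and 2.36 on the log2 scale. Of MHC class I genes 16 of 20 rose (adjusted p = 6.48e-28, adjusted p = 0.169 with an estimated correlation; 20 adjusted over the list alone) and of stress genes 8 of 21 fell (adjusted p = 6.64e-09, adjusted p = 0.513 with an estimated correlation; 11 lower and 1 higher adjusted over the list alone). Endothelial markers lay at a median of 5.96% of their endothelial level in TDB pDC-like cells, Cxcl9 at 5.59% and Gbp2 at 11.1%, so their rises there were not separated from endothelial RNA carried along. Of 22 interferon gamma genes that were higher in pDC-like cells, 10 lay above 2 times the level of the markers, and of MHC class I genes all 16. The count was 105, 117, 106 and 63 without vehicle 1, vehicle 4, TDB 4 and TDB 5, and 118 with the replicate block. In B cells 177 of 6325 genes changed (128 higher and 49 lower), with Serpina3g at 6.64 ± 0.46 (3.72 ± 2.01 to 409 ± 186 CPM), Gbp7 at 4.97 ± 0.31, Zbp1 at 4.54 ± 0.33 and Tsc22d3 at -1.55 ± 0.25. MHC class I genes had 16 of 19 higher, such as Psmb9 (2.44 ± 0.14), the only list of any class whose call held with an estimated correlation (adjusted p = 1.21e-37, or adjusted p = 0.0456 with an estimated correlation; 19 adjusted over the list alone). For interferon gamma, 28 of 31 genes were higher (adjusted p = 1.11e-51, adjusted p = 0.0732 with an estimated correlation; 28 adjusted over the list alone). The B cell count was 105 without TDB 5 and 291 with the replicate block. In simulated monocyte-like, neutrophil-like, pDC-like and B cell sums 29.9%, 34.3%, 59.7% and 61.2% of genes changed 2-fold were recovered.

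**Figure D3:**
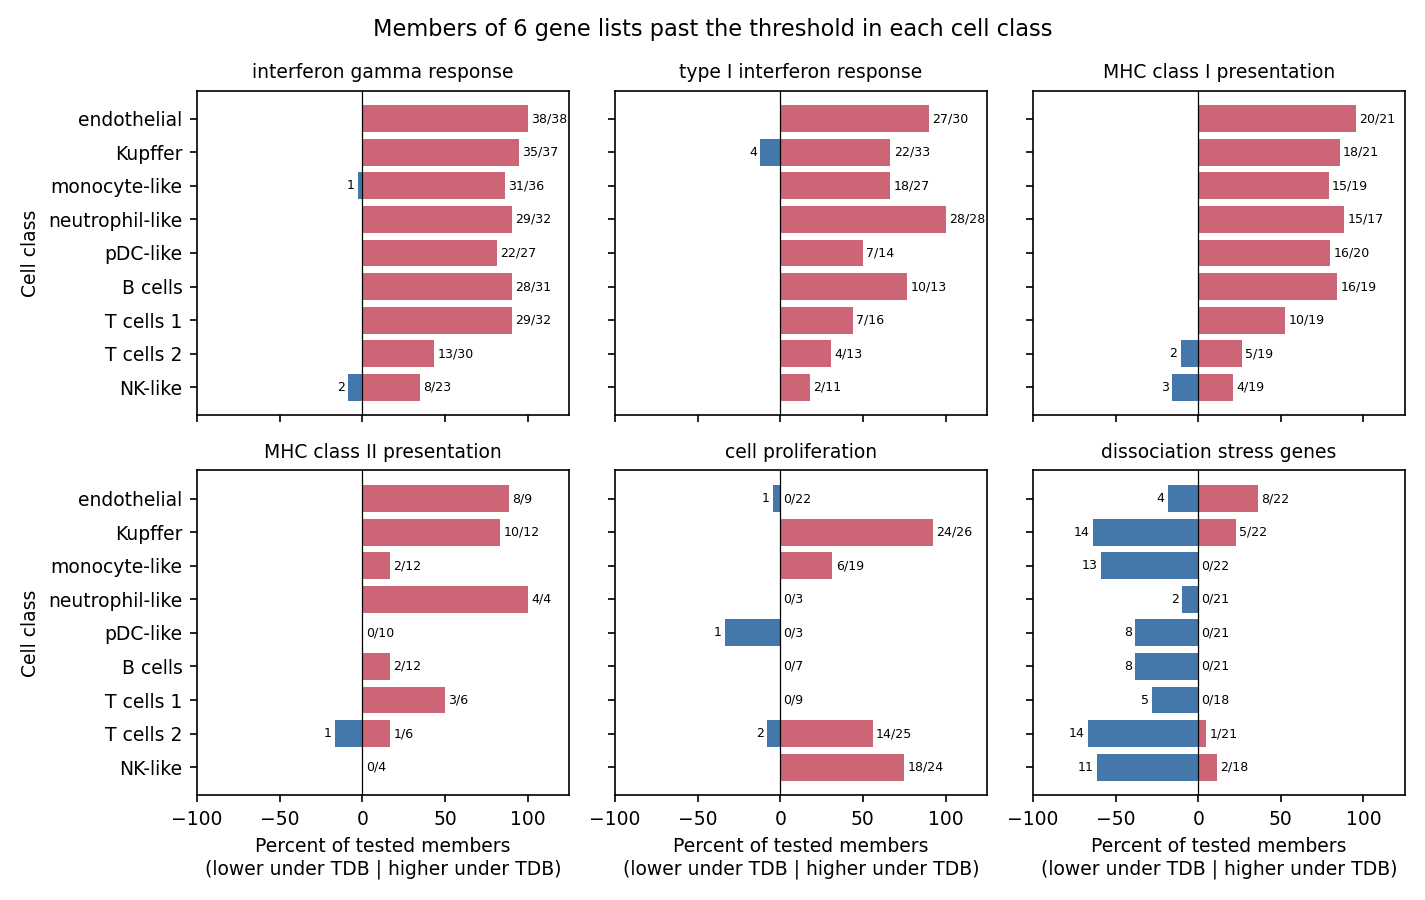
Percent of the tested members of 6 gene lists that were higher or lower after TDB, past the threshold, in 9 cell classes with 3 mice per group. The interferon gamma list has all 38 members higher in endothelial cells and 8 of 23 in NK-like cells.

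Over all cells, 4246 of 16042 genes changed, 2596 higher and 1650 lower, with Cxcl9 at 6.17 ± 0.33 (29.4 ± 8.32 to 2120 ± 512 CPM, adjusted p = 0.000471) and Cxcl10 at 5.53 ± 0.40 leading the rises, and Cd163 (-2.71 ± 0.50), Btnl9 (-2.34 ± 0.28), Lhfpl2 (-2.21 ± 0.16) and Itga8 (-2.06 ± 0.27) the falls. The count was 2172 without vehicle 4 and 2692 without vehicle 5. These sums mix changes within cells with changes in cell shares. Interferon gamma genes had 36 of 38 higher (adjusted p = 5.76e-29, adjusted p = 0.431 with an estimated correlation; 37 adjusted over the list alone) and sinusoidal genes 12 of 22 lower (adjusted p = 8.75e-06, adjusted p = 0.595 with an estimated correlation; 14 adjusted over the list alone). In simulated sums 44.8% of genes changed 2-fold were recovered.

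The last comparison asked whether the makeup of the liver suspension differed. In the main edgeR fit, 0 of 14 classes passed the threshold and 0 had an unadjusted p under 0.05. No alternative gave a call. Monocyte-like cells had the lowest p in the main fit (0.0538, adjusted 0.753), with 1.97 ± 0.763% of cells in vehicle and 4.69 ± 3.25% in TDB mice (log2 ratio 1.25 ± 0.57, exact permutation p = 0.2, n = 3). Their log2 ratio was 0.52 ± 0.53 without TDB 1, which held 8.44%. Over the alternatives their unadjusted edgeR p was 0.0152 (replicate block, adjusted 0.213) to 0.351 (without TDB 1). Unadjusted edgeR p was also 0.0455 for NK-like cells with own clustering and 0.0298 for neutrophil-like cells without vehicle 1. T cells made up 11.5 ± 2.16% and 17.2 ± 9.34% (exact permutation p = 0.5), with 27.0% in TDB 4 and 8.41% in TDB 5. Endothelial cells made up 49.0 ± 7.65% and 44.9 ± 10.6%, Kupffer cells 15.01 ± 4.00% and 12.8 ± 5.26%, and NK-like cells 3.73 ± 0.992% and 2.29 ± 0.997% (exact permutation p = 0.6, 0.6 and 0.2). An exact test of 3 against 3 mice cannot give a p under 0.1, and shares depend on how well each cell type survived dissociation.

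**Figure D4:**
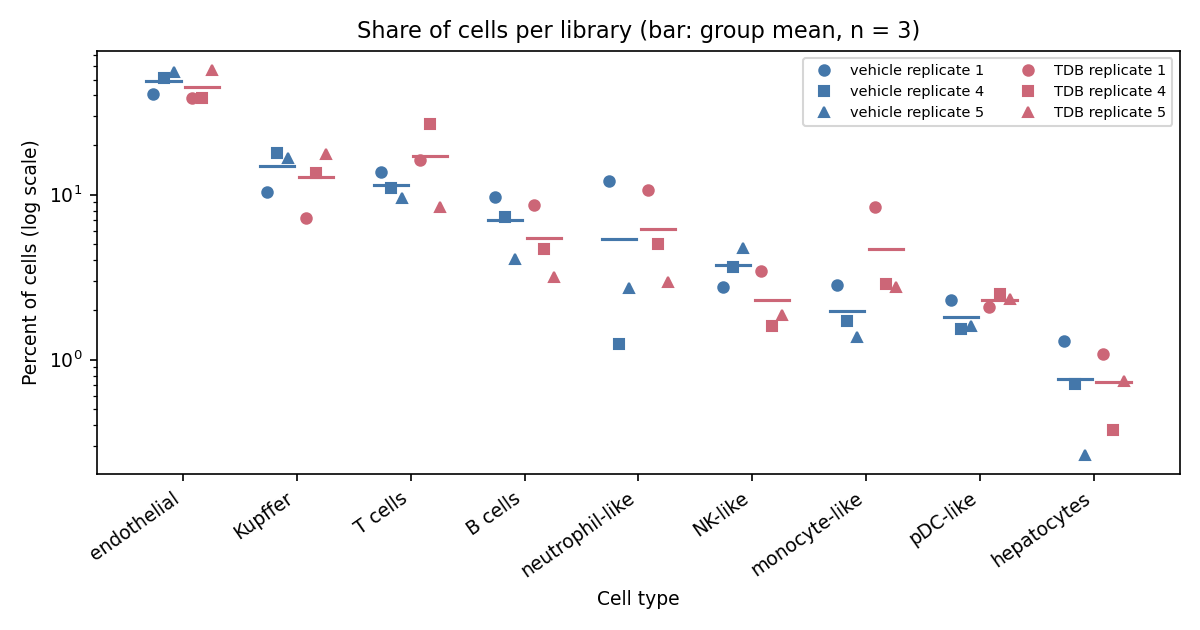
Percent of all cells of a library, on a log scale, for 9 cell types, 1 point per library in 3 vehicle and 3 TDB mice. Monocyte-like cells lie between 1.37% and 2.83% in vehicle and between 2.75% and 8.44% in TDB mice.

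Coordinates of the main endothelial genes, in GRCm38, were as follows; all are protein-coding genes in GENCODE M21 and the counts cover whole genes. Cxcl9 (ENSMUSG00000029417) lies on chromosome 5 from 92321347 to 92328079 on the minus strand, next to Cxcl10 (ENSMUSG00000034855), from 92346638 to 92348889. Cd274 (ENSMUSG00000016496) lies on chromosome 19 from 29367455 to 29388095, Vcam1 (ENSMUSG00000027962) on chromosome 3 from 116109949 to 116129688 and Icam1 (ENSMUSG00000037405) on chromosome 9 from 21015985 to 21028817. Igtp (ENSMUSG00000078853) spans chromosome 11 from 58199556 to 58207591, Btnl9 (ENSMUSG00000040283) chromosome 11 from 49165585 to 49187159 and Stab2 (ENSMUSG00000035459) chromosome 10 from 86841198 to 87008025.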

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

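The splits of the mice in this part were counted after the results had been seen. A test of the difference picked out 7 results, the numbers of genes whose response in endothelium differed from that in another cell type: 600 for T cells, 1113 for NK-like, 4923 for Kupffer, 221 for monocyte-like, 249 for neutrophil-like, 194 for pDC-like and 249 for B cells. Grouping 3 against 3 gives 10 splits, too few for a share under 0.05. The real split gave the largest count, the 1 of 10 as large, in all 7; the highest other count was 1, 3, 0, 0, 43, 7 and 6 in the same order.

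The counts of changed genes within cell types were also largest in the real split, 1 of 10, in endothelial, T, T cells 1, T cells 2, NK-like, Kupffer, monocyte-like, neutrophil-like, pDC-like, B and all cells. The highest other count was 3 in pDC-like cells and 0 elsewhere. Splits other than the real one put TDB mice on both sides, which adds spread within groups, and 3 of them part all same-numbered pairs as the real one does. In those 3 the count was 0 in every class. List tests past the threshold over all classes numbered 111 in the real split and 113 in another, so 2 of 10 splits were as large. Abundance gave 0 classes in the real split and up to 3 in another; with a real count of 0, 10 of 10 splits are as large whatever the data, so this count, planned before, decides nothing.

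Signal in cells outside the comparisons picked out 6 results, with the CPM of the interferon gamma list summed per mouse. The ratio of TDB to vehicle was 9.54 in hepatocytes, 5.16 in T cells 4, 7.48 in EC/T, 4.54 in M6, 3.19 in M7 and 15.1 in M8. All 3 TDB mice lay above all 3 vehicle mice in each class (exact permutation p = 0.1, the lowest that 3 against 3 can give). The classes held 80 and 81, 240 and 201, 107 and 81, 40 and 37, 37 and 37, and 30 and 26 cells in vehicle and TDB mice. EC/T and M8 carry endothelial RNA: own clusters placed 157 of 188 and 52 of 56 of their cells with endothelial cells, and 73.9% and 69.6% were called doublets. Carried endothelial RNA was not measured in the other classes and is not excluded there. Cxcl9, which rose strongly in endothelium, was at 411 ± 241.5 CPM in TDB hepatocytes and 668.1 ± 895.8 CPM in TDB cells of M6. The ratio of M6 was 2.86 without TDB 1.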

How the results depend on the processing

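Of 208 named genes 190 passed the threshold, 153 of them in every setting and 160 in every setting except the test against a 1.5-fold change. Apart from those chosen in advance, named genes were picked because they had passed with large fold changes. These numbers therefore do not describe the calls in general. Of 37 named differences between cell types 32 passed, 24 in every setting. Settings with EC/T, with M8, without EC6, without Kupffer5, with deep classes only and with all 4 T cell classes were chosen after seeing the data and kept every count of changed genes within 1.5 times. Among named genes the replicate block brought Kdr in endothelium, Cd69 (-0.67) and Mki67 (1.29) in T cells, and Ccr7 and Mki67 in T cells 2 past the threshold and changed no other call. Of list calls it ended those of chemokines in monocyte-like (adjusted p = 0.0653) and neutrophil-like cells (0.0927) and of proliferation in pDC-like cells (0.063), and added the sinusoidal and red cell lists in endothelium, mitochondrial genes in T cells (0.0307), chemokines and the T cell receptor in T cells 1 (0.0335 each), apoptosis in T cells 2 (0.0439), hepatocyte markers in Kupffer (0.0168), homing receptors in monocyte-like (0.0191), stellate genes in neutrophil-like (0.0243), pericentral (0.0155) and neutrophil genes (0.00588) in pDC-like, and the T cell receptor (0.00741), acute phase (0.021) and neutrophil genes (0.0402) in all cells. In simulated sums 29.9% of 2-fold changes were recovered in monocyte-like and 76.1% in endothelial cells. For the changes listed here, the cause was not tested.

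With DESeq2's Wald test the genes changed were 105 in T cells 1, 1006 in T cells 2, 606 in NK-like and 118 in pDC-like cells. With equal cells per library they were 90, 752 and 653 in the first 3 of these, 503 in monocyte-like, 150 in neutrophil-like and 83 in pDC-like cells, and Selp in endothelium was at 0.006, Cd34 at 0.03 and Mki67 in T cells 2 at -0.065. Against a 1.5-fold change they were 453, 30, 29, 410, 220, 2303, 220, 200, 34, 75 and 826 in endothelial, T, T cells 1, T cells 2, NK-like, Kupffer, monocyte-like, neutrophil-like, pDC-like, B and all cells. With no filter on low counts they were 1147 in T cells, 289 in T cells 1, 1254 in monocyte-like, 463 in pDC-like and 344 in B cells. With the replicate block they were 3528 in endothelial, 900 in T cells, 255 in T cells 1, 118 in pDC-like and 291 in B cells, log2 ratios of cell shares were 0.088 for hepatocytes, 0.173 for M7 and 0.033 for M8, and Il2ra in T cells was at -0.061. With TMM over classes those shares were 0.044, 0.224 and 0.009. Without called doublets pDC-like cells had 307 changed genes, M7 a share ratio of 0.300 and Il2ra -0.003; Il2ra was at -0.004 with DESeq2 size factors and -0.02 with the stricter quality filter, and Cd3e at 0.072 with all 4 T cell classes. Lists called with an estimated correlation were 1 in B cells and 0 in endothelial, T, T cells 1, T cells 2, NK-like, Kupffer, monocyte-like, neutrophil-like, pDC-like and all cells, and by fry 5 in T cells, 2 in T cells 1, 7 in monocyte-like, 4 in pDC-like and 7 in B cells.

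On leaving out each library in turn, the lowest and highest numbers of changed genes were 940 and 2089 in endothelial, 37 and 928 in T, 61 and 177 in T cells 1, 1043 and 1649 in T cells 2, 795 and 1277 in NK-like, 364 and 802 in monocyte-like, 256 and 451 in neutrophil-like, 63 and 153 in pDC-like, 105 and 201 in B and 2172 and 3426 in all cells. Genes whose response differed from endothelium numbered 230 and 630 for T, 110 and 563 for monocyte-like, 127 and 201 for neutrophil-like, 77 and 197 for pDC-like and 148 and 377 for B cells, and lists called 5 and 12 in NK-like and 5 and 14 in pDC-like cells. Share ratios were -0.459 and 0.588 for hepatocytes, -0.066 and 0.349 for M6, -0.379 and 1.048 for M7, -0.774 and 1.315 for M8, -0.435 and 1.629 for neutrophil-like cells, -0.434 and 0.178 for T cells 4 and -0.535 and 0.053 for Kupffer cells. In endothelium Sele lay at -0.874 and 0.334 and Cd34 at -0.136 and 0.157; in T cells Cd3e lay at -0.202 and 0.018, Il2ra at -0.486 and 0.346 and Ifng at -1.03 and 0.446. The difference between endothelial and neutrophil-like cells lay at -4.68 and 1.92 for H2-DMa and -1.53 and 0.966 for Igtp.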

Other observations

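Hepatocytes were too few for the gene tests, with 80 vehicle and 81 TDB cells, and are given as sums per mouse. The acute phase gene Saa1 was at 543.9 ± 346.5 CPM in vehicle and 4693 ± 4353 CPM in TDB hepatocytes (mean ± SD), a ratio of 8.63 (exact permutation p = 0.1, n = 3), of 4.15 without TDB 4 and of 13.6 without vehicle 5. Cyp2e1, a drug-metabolising enzyme of pericentral hepatocytes, was at 3359 ± 2227 and 560.3 ± 554.7 CPM, a ratio of 0.167 (exact permutation p = 0.1), of 0.0722 without TDB 5 and of 0.261 without vehicle 5, and Alb at a ratio of 1.04 (exact permutation p = 0.8). T cells 1 had 890 cells in TDB 4 and 187 to 333 in each other library.

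Sinusoidal endothelial genes were lower in Kupffer sums, 18 of them with a median log2 fold change of -1.59; the tests of this pattern were written before their values were seen. Endothelial RNA carried by the cells of Kupffer5, present in vehicle mice only, was tested by leaving them out: 5 of the 18 stayed lower, 11 were higher, and the median was 1.00. The 5 were Fcna, Mrc1, Maf, Cd209b and Ctsl. The calls of the other genes as lower thus rested on the cells of Kupffer5. Kupffer5 held vehicle cells alone, so leaving it out changed a single group. Whether endothelial RNA in these cells was the cause could therefore not be decided. Without cells called doublets 16 stayed lower (median -1.49), which argues against called doublets as the whole source; 35.6% of Kupffer5 were called, so mixed cells that were not called stay open. Free endothelial RNA could not be told apart, with a median of -0.66 over 46 pairs of gene and other cell type, 5 lower and 0 higher past the threshold.

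Bile duct and red cell genes fell in endothelial sums; the tests were chosen after seeing this, except that of free RNA. A few vehicle cells rich in this RNA could explain the falls: the 10 cells with most counts held at least 73.5% of the vehicle counts of each of Spp1, Clu, Hbb-bs and Hba-a1. Hbb-bs and Hba-a1 were among the leading genes of EC5 and not of EC6, so leaving out EC6 could change little for them. From EC1 to EC3 alone, without EC5, they were still lower (-3.426 and -2.475). The cells of EC6 did not explain the red cell genes, since 3 of 3 haemoglobin genes stayed lower without them. For the bile duct genes the part of EC6 could not be decided (median of Spp1 and Clu -2.55 without EC6). Free RNA of bile duct and red cells could not be decided either (median -0.27 over 5 pairs of gene and other cell type). No biological explanation was tested.

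Immediate-early members of the stress list were lower in 28 of 48 pairs of gene and class in T cells 1, T cells 2, NK-like, pDC-like and B cells, and higher in 0 (median -0.94): 2 of 9 in T cells 1, 9 of 10 in T cells 2, 7 of 9 in NK-like, 4 of 10 in pDC-like and 6 of 10 in B cells. Less dissociation stress in the TDB suspensions, a test chosen after seeing this, could not be decided: heat shock members had a median of -0.40 over 37 pairs, 13 lower and 3 higher. The 13 lower pairs were all of Dnajb1, Hspa1a and Hspa1b, and the 3 higher pairs of Hspa8 and Hsp90ab1. The median thus pooled genes that went opposite ways. A lower glucocorticoid signal after TDB, written before, could not be decided either, with 8 of 24 pairs of glucocorticoid target and class lower and 0 higher. Tsc22d3, a glucocorticoid-induced gene that fell in T cells 1 and B cells, was not among the targets counted. T cells 2 and NK-like cells held more counts per cell after TDB, so their falls in CPM do not by themselves show falls per cell.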
